A study of Mus musculus with 30 samples.

How the data were processed

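RNA was measured in 30 libraries of cultured mouse osteoclasts, 3 in each of 10 groups. Per the labels' protocols, total RNA was extracted with a Nucleospin kit, polyadenylated RNA was selected with oligo(dT), and libraries were sequenced on an Illumina NovaSeq 6000. The values deposited by the authors are whole-number counts per gene and library, not normalized. Per the file headers, fragments were counted with featureCounts 1.6.0 over the exons of each gene of the Ensembl 88 annotation of GRCm38, from read pairs aligned and sorted by STAR. The submitters' processing notes name HTSeq, without a version, and mm10 instead. The headers, which record the commands, were followed. No option for strand is recorded, so reads of a gene and of an overlapping antisense gene cannot be told apart, and no option for multimapping reads is recorded, so genes with near-identical copies lose or share reads. The STAR version and read trimming are not given.

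Each file listed the same 50686 genes, with no row for unassigned reads, and 99.56% of the gene identifiers carried a symbol. Coordinates below are GRCm38, 1-based, from the annotation in the files. Total counts per library ranged from 4269798 to 25147975, which was the depth used for CPM, the counts of a gene scaled to a library total of 1e6. A count of 0 was read as at most 3 counts, a limit that covers counting error only, since the libraries carry no molecular identifiers.

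Groups were taken from sample titles: genotype, age, stage of culture and, where present, the number 519 or a tag beginning with D1 in the title. The labels explain neither, so libraries that carry them were kept as groups of their own (set 519 and set D1) and the other libraries are called unprefixed. Replicate numbers in the titles are not stated to mark separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical. Counts of every replicate pair differed by more than sampling noise, with chi-square per degree of freedom from 1.28 to 22.3 over genes with at least 50 counts in the pair. No library is therefore a copy of another's counts, but repeat libraries of 1 culture are not excluded.

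Counts were scaled by TMM and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test, with 1 coefficient per group over all 30 libraries. Genes were kept by filterByExpr, which left 15310 genes and removed 35376. The common biological coefficient of variation was 0.0610. All adjusted p for genes are Benjamini-Hochberg values from this test over the 15310 genes of a comparison, with a threshold of 0.05. Fold changes are moderated by edgeR's default prior count. Gene levels are means ± SD of TMM-scaled CPM over the 3 libraries of a group unless the CPM of the library total is named. In parentheses after each fold stands the log2 fold change ± its standard error. A gene is said to have risen, fallen or changed only where its adjusted p passed the threshold, and a list where its camera test passed, which does not mean that each member changed.

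Before the data were examined, 37 gene lists, the comparisons, the tests and the rule for named genes were fixed. The lists cover osteoclast resorption and acid secretion, osteoclast fusion, RANK signalling and osteoclast transcription factors, osteoclast repressors, V-ATPase subunits, lysosome, and osteoclast-derived coupling factors. Immune and stress lists cover macrophage and monocyte markers, complement C1q and tissue macrophage genes, MHC class II antigen presentation, interferon-stimulated genes, inflammatory cytokines and the senescence-associated secretory phenotype (SASP), NF-kB feedback genes, NRF2 and oxidative stress, unfolded protein and integrated stress response, and heat shock and immediate early genes. Growth lists cover p53 targets, cyclin-dependent kinase inhibitors and senescence, telomerase and telomere maintenance, DNA damage response and repair, cell cycle, ribosomal proteins and histones. Metabolic lists cover oxidative phosphorylation (nuclear and mitochondrial genes apart), glycolysis and hypoxia, cholesterol synthesis, and LXR and lipid handling. Markers of other cells cover T and NK, B and plasma, neutrophil, erythroid and platelet, mast and basophil, dendritic, stromal, and endothelial cells, and the last list holds sex-linked genes. Each list was tested in each comparison with camera (limma, log2 CPM with a prior count of 2) at a preset correlation of 0.01, adjusted over the lists of that comparison. Lists with fewer than 5 measured members were counted but not tested. Where a call was lost when the correlation was estimated from the data, that adjusted p follows it after the word estimated. Calls with no such p held with an estimated correlation, except values from other title sets, for which none was estimated.

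Named genes were the top genes of a comparison (adjusted p under 0.05, mean of at least 5 CPM in a compared group, no overlap of libraries outside interactions, no predicted model, pseudogene or antigen receptor segment), 8 per direction in the 4 main comparisons and 3 in the others. To these were added the 3 members with the smallest adjusted p of each list described, and 9 fixed genes in the main comparisons (Terc, Acp5, Ctsk, Mmp9, Nfatc1, Dcstamp, Calcr, Cdkn1a and Cdkn2a). The main comparisons were KO vs WT at 1 and at 6 months, WT at 20 vs 1 month, and multinucleated vs 2-day cultures of 6-month WT. Gm47015, Gm8189, Vmn2r96, Eif2s3x, Uty, Maoa, Cd55, Als2cl and Npdc1 lie outside this rule and were chosen after their values were seen. Some genes named by the rule are not reported here and were left out of the alternatives.

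The test was checked on simulated counts of 14764 genes, 200 of them changed for KO vs WT at 1 month. Real comparisons called far more, so its error there was not tested. Of genes changed 1.5-fold 53 of 67 were recovered, of those changed 2-fold 65 of 67, and 4-fold 66 of 66. Of 14564 unchanged genes 12 were called. The 1 changed list was called and none of 36 unchanged lists. For WT at 20 vs 6 months, where no gene was changed, 0 were called.

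Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, only the compared groups in the fit, the replicate number as a block, leaving out each library in turn, other title sets, the estimated correlation and, for correlations between comparisons, genes of mean log2 CPM 3 or more. Set D1 as 1-month WT in the WT ages, the interaction and these correlations, set 519 as KO of both ages, thinning all libraries to 4269798 counts, removing each library's trend on gene length (loess, span 0.5) and leaving out both unprefixed 1-month libraries numbered 1 were chosen after seeing the data. For agreement between comparisons, Spearman correlations were taken across genes, which are not independent replicates, for 6 pairs of comparisons with no library in common. A 3 v 3 comparison of a single value cannot give an exact p under 0.1.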

Results

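Osteoclasts, the bone-resorbing cells that form by fusion of macrophage-lineage precursors, were cultured from bone marrow-derived macrophages of C57BL/6J mice. Donors were wild type (WT) or lacked Terc, the RNA template of telomerase (Terc-/-, here KO). Cells received M-CSF at 25 ng/ml and RANKL at 100 ng/ml, the cytokines that drive osteoclast formation, in medium with 10% FBS, either for 2 days or until large multinucleated cells had formed. Multinucleated cultures came from 1-month and 6-month donors of both genotypes and from 20-month WT donors, and 2-day cultures from 6-month and 20-month WT donors. The stated aim was to ask whether osteoclasts of different donor ages, with or without Terc, differ in gene expression. Set 519 added KO multinucleated cultures of 1 and 6 months, and set D1 added 1-month WT multinucleated cultures. Libraries of set 519 held 4269798 to 12987993 counts and the other 24 libraries 13182063 to 25147975.

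Terc (ENSMUSG00000064796, chromosome 3, 96414437-96414859, minus strand, a 423 bp gene without introns annotated as misc_RNA) was at the detection limit in every library. The 18 WT libraries held 5 Terc counts in all, spread over 3 libraries (0.0150 CPM of the library total), and the other 15 held 0. The 12 KO libraries held 0, which allows up to 0.0162 CPM. The loss of Terc in KO was not detectable at this depth in polyadenylated RNA, so the genotype labels rest on the titles alone. Y-linked genes were counted in 27 libraries. Set D1 alone had the pattern of female cells. Xist, the RNA of the inactive X chromosome, stood at 851 ± 49.6 CPM of the library total, and Ddx3y, Eif2s3y, Kdm5d and Uty at 0 counts. Contrasts with set D1 thus also compare sexes.

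In a principal component analysis of log2 CPM, the first component held 34.6% of the variance and the second 25.4%. On the first component the means of the 4 KO groups and unprefixed 1-month WT lay between -60.3 and -28.9. The other groups lay between 34.9 and 53.1. On the second, multinucleated WT lay at 12.9 (6 months), 16.2 (20 months), -29.4 (unprefixed 1 month) and 66.3 (set D1), and 2-day WT at -56.3 and -47.1.

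**Figure D1:**
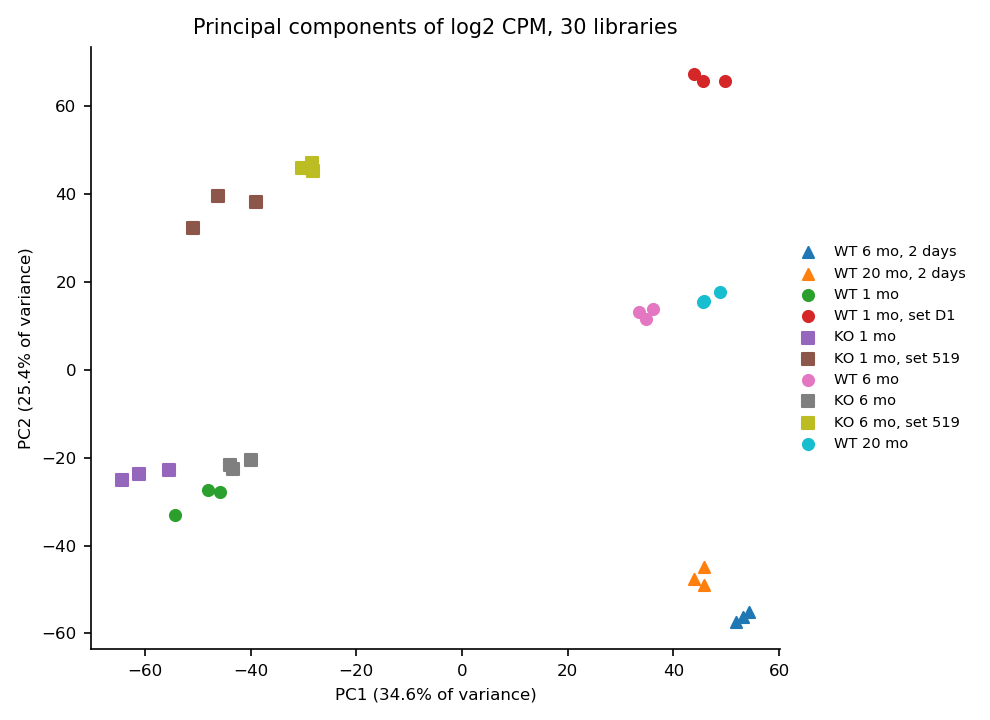
Scores of the 30 libraries on the first principal component (horizontal, 34.6% of variance) and the second (vertical, 25.4%) of log2 CPM, coloured by group. Group means of KO and unprefixed 1-month WT lie to the left.

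The comparison of KO with WT at 1 month asked how the loss of Terc changes osteoclasts of young mice. Genes of bone resorption were lower in KO. Ctsk (ENSMUSG00000028111, chromosome 3, 95499256-95509362), the main collagen-degrading protease of osteoclasts, was 7.68-fold lower (-2.94 ± 0.09, adjusted p = 3.3e-23), at 72.6 ± 14.5 CPM against 559 ± 8.61 CPM. Acp5, the tartrate-resistant acid phosphatase (ENSMUSG00000001348, chromosome 9, 22126727-22135711), was 5.36-fold lower (-2.42 ± 0.09, adjusted p = 6.4e-21), at 90.0 ± 7.51 CPM against 483 ± 14.7 CPM. Car2, the carbonic anhydrase that supplies protons for acid secretion, was 10.6-fold lower (-3.40 ± 0.14), and the gelatinase Mmp9 (ENSMUSG00000017737, chromosome 2, 164940780-164955850) 2.59-fold lower (-1.37 ± 0.06). Where 1 pair of counts is given for a list, the counts adjusted over the list alone were the same. Of the resorption and acid secretion list, 16 of 20 measured members fell and 3 rose (17 fell and 3 rose adjusted over the list alone, adjusted p = 1.5e-11). Both groups lay below the 2-day WT cultures in Ctsk and Mmp9. Ctsk was at most 568 CPM in any of their libraries, against at least 1021 CPM at 2 days, and Mmp9 at most 830 against at least 1247 CPM. Genotype was therefore not told apart from how far the cultures had matured. Fusion genes fell as a list (10 of 15 lower, 5 higher, adjusted p = 0.0082), among them the fusion receptors Dcstamp, 4.01-fold lower (-2.0 ± 0.07), and Ocstamp, 4.95-fold lower (-2.31 ± 0.10), and the receptor kinase Mst1r, 10.3-fold lower (-3.37 ± 0.13). RANK signalling genes were lower too (14 of 25 lower, 6 higher, adjusted p = 2.4e-04, estimated 0.097): Nfatc1, the main transcription factor of osteoclast formation (ENSMUSG00000033016, chromosome 18, 80606205-80713071), was 3.01-fold lower (-1.59 ± 0.08) and Jdp2 3.72-fold lower (-1.89 ± 0.06). Repressors of osteoclast formation rose (10 of 13 higher, 1 lower, adjusted p = 8.9e-05). Irf8 was 1.73-fold higher (0.79 ± 0.06). V-ATPase subunits did not pass as a list (4 of 18 lower, 3 higher, adjusted p = 0.85).

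Macrophage genes were higher in 1-month KO than WT. Macrophage and monocyte markers rose (18 of 24 higher, 2 lower, 19 and 2 adjusted over the list alone, adjusted p = 1.0e-09). The scavenger receptor Cd36 was 2.30-fold higher (1.20 ± 0.05) and the efferocytosis receptor Mertk 2.35-fold higher (1.24 ± 0.07). Complement C1q and tissue macrophage genes rose (15 of 18 higher, 2 lower, adjusted p = 1.8e-09), among them the macrophage secreted protein Cd5l, 4.32-fold higher (2.11 ± 0.08). Outside that list, the iron exporter Slc40a1 was 3.92-fold higher (1.97 ± 0.08). Lysosomal genes rose (22 of 26 higher, 0 lower, 23 and 0 adjusted over the list alone, adjusted p = 5.3e-14), including the cathepsins Ctsh, 2.24-fold higher (1.17 ± 0.07), and Ctsb, 1.72-fold higher (0.78 ± 0.05). LXR and lipid genes (11 of 17 higher, 4 lower, adjusted p = 1.9e-04), NRF2 genes (13 of 23 higher, 2 lower, 14 and 2 adjusted over the list alone, adjusted p = 4.5e-07, estimated 0.078) and inflammatory cytokines and SASP genes (20 of 32 higher, 0 lower, 20 and 1 adjusted over the list alone, adjusted p = 4.9e-07) rose as well, with heme oxygenase Hmox1 2.35-fold higher (1.23 ± 0.07) and collagenase Mmp13 3.13-fold higher (1.65 ± 0.12). Rasgrp2, a Rap guanine exchange factor, was 6.53-fold higher (2.71 ± 0.24). Beside these, markers of stromal cells were higher in KO (10 of 21 higher, 1 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.025, estimated 0.37). The matrix protein Dcn was 4.73-fold higher (2.24 ± 0.12), and of 6 neutrophil markers 4 were higher, with lipocalin Lcn2 2.79-fold higher (1.48 ± 0.16). Interferon-stimulated genes (10 of 40 higher, 2 lower, 8 and 2 adjusted over the list alone, adjusted p = 0.16), MHC class II genes (5 of 12 higher, 4 lower, adjusted p = 0.73) and dendritic markers (3 of 11 higher, 0 lower, adjusted p = 0.29) did not pass.

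Genes of the p53 pathway, which responds to DNA damage and short telomeres, were higher in 1-month KO. Of 34, 19 rose and 3 fell (20 and 3 adjusted over the list alone, adjusted p = 4.9e-05). In all title sets the list mean was higher in each KO library than in multinucleated WT of its age. Polo-like kinase Plk2 was 2.32-fold higher (1.21 ± 0.06), the epoxide hydrolase Ephx1 1.66-fold higher (0.73 ± 0.06), the death receptor Eda2r 3.0-fold higher (1.58 ± 0.18) and the cell cycle inhibitor Cdkn1a 1.32-fold higher (0.40 ± 0.05). Cdkn2a, a senescence marker, did not pass in unprefixed libraries, at 1.09-fold higher (0.13 ± 0.10, adjusted p = 0.35). Cell cycle genes fell (35 of 39 lower, 1 higher, adjusted p = 1.1e-19). Cyclin Ccnb1 was 1.83-fold lower (-0.87 ± 0.05) and the mitotic activator Cdc20 2.03-fold lower (-1.02 ± 0.07). Telomere maintenance genes fell (11 of 26 lower, 0 higher, adjusted p = 0.0034), among them the telomerase component Dkc1, 1.79-fold lower (-0.84 ± 0.06). DNA repair genes (20 of 31 lower, 0 higher, 21 and 0 adjusted over the list alone, adjusted p = 1.3e-04), ribosomal protein genes (71 of 81 lower, 0 higher, 74 and 0 adjusted over the list alone, adjusted p = 3.4e-13, estimated 0.36) and nuclear genes of oxidative phosphorylation (29 of 48 lower, 1 higher, 31 and 2 adjusted over the list alone, adjusted p = 2.0e-06, estimated 0.42) fell. The list of cell cycle inhibitors and senescence genes (6 of 15 lower, 3 higher, 6 and 4 adjusted over the list alone, adjusted p = 0.32) and that of mitochondrial genome transcripts (5 of 13 lower, 1 higher, adjusted p = 0.12) did not pass.

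In all, 6340 of 15310 genes passed between KO and WT at 1 month, 3162 higher and 3178 lower. The choice of title set turned several directions past the threshold and ended other calls. With set 519 KO against unprefixed WT, the log2 fold change was 1.34 for Ctsk, 1.71 for Acp5, 2.12 for Mmp9, 0.51 for Mst1r, -3.30 for Lcn2 and -0.55 for Mmp13. List medians were 0.62 against -0.60 for resorption and -0.90 against 0.69 for SASP genes. Calls were lost for Dcstamp (0.095), Car2 (-0.21), Ocstamp (-0.13), Ctsh (0.066) and Cdkn1a (0.053), and for the fusion, RANK signalling, repressor, macrophage, C1q, NRF2, stromal and neutrophil lists. Cdkn2a passed, at 1.24. With the female set D1 as WT, medians for unprefixed KO and set 519 KO were 2.05 and 0.71 against -0.60 for cell cycle and -2.52 and -2.69 for stromal genes. Ribosomal genes, Eda2r, Ccnb1 and Cdc20 also turned with both. Telomere and DNA repair genes, Dcn and Dkc1 turned with unprefixed KO and lost their calls with set 519 KO, with which SASP genes, Rasgrp2, Ctsh, Mmp13 and Lcn2 turned. Calls were lost with both KO sets for the coupling factor, fusion, RANK signalling, repressor and neutrophil lists, with unprefixed KO for nuclear oxidative phosphorylation, and with set 519 KO for Plk2 (0.11) and macrophage, C1q and NRF2 genes. With both sets on each side the stromal median was -1.15, Lcn2 turned, and 10 list calls and those of Ccnb1 and Cdc20 were lost.

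In 6-month donors, resorption genes were again lower in unprefixed KO than in WT. Mmp9 was 11.6-fold lower (-3.53 ± 0.07, adjusted p = 4.3e-29), at 782 ± 62.0 CPM against 9054 ± 642 CPM. Ctsk was 9.21-fold lower (-3.20 ± 0.08), Acp5 7.70-fold lower (-2.95 ± 0.09), the calcitonin receptor Calcr (ENSMUSG00000023964, chromosome 6, 3685680-3764714) 68.5-fold lower (-6.10 ± 0.13), the attachment integrin Itgb3 6.86-fold lower (-2.78 ± 0.07), and the costimulatory receptor Oscar 11.6-fold lower (-3.53 ± 0.11). Of the resorption list 19 of 20 measured members fell and 0 rose (adjusted p = 5.1e-17). V-ATPase subunits fell (12 of 18 lower, 2 higher, adjusted p = 1.6e-05, estimated 0.095). Fusion genes did not pass as a list (7 of 15 lower, 6 higher, 8 and 6 adjusted over the list alone, adjusted p = 0.40), although Dcstamp was 3.28-fold lower (-1.71 ± 0.07). RANK signalling genes went both ways (13 of 25 higher, 10 lower, adjusted p = 0.97), with a median log2 fold change of 0.15 while the camera direction was down, and Nfatc1 was 1.95-fold lower (-0.97 ± 0.07). Repressors were higher (9 of 13 higher, 4 lower, adjusted p = 0.0065, estimated 0.060). Akr1c18, a steroid reductase, was 25.0-fold lower (-4.64 ± 0.10) and the metalloreductase Steap4 64.6-fold lower (-6.01 ± 0.16).

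All 40 interferon-stimulated genes were higher in 6-month KO than in 6-month WT (adjusted p = 2.9e-25, estimated 0.067). Their median log2 fold change was 2.43. The interferon signalling factor Stat2 was 5.42-fold higher (2.44 ± 0.09), the DNA sensor family member Ifi204 4.54-fold higher (2.18 ± 0.09), and the surface antigen Ly6a 13.1-fold higher (3.71 ± 0.11). Inflammatory and SASP genes rose (27 of 32 higher, 3 lower, adjusted p = 9.0e-09). The chemokine Ccl5 was 18.7-fold higher (4.22 ± 0.18) and the chemokine Ccl2 7.59-fold higher (2.92 ± 0.13). NF-kB genes rose (14 of 18 higher, 1 lower, 15 and 1 adjusted over the list alone, adjusted p = 9.3e-05, estimated 0.086). Macrophage markers rose (20 of 24 higher, 2 lower, adjusted p = 1.5e-07), with Adgre1, which encodes F4/80, 3.51-fold higher (1.81 ± 0.05) and lysozyme Lyz2 2.85-fold higher (1.51 ± 0.05). C1q and tissue macrophage genes (14 of 18 higher, 1 lower, 14 and 2 adjusted over the list alone, adjusted p = 1.6e-05, estimated 0.10), lysosomal genes (20 of 26 higher, 3 lower, adjusted p = 1.2e-05, estimated 0.23) and NRF2 genes (19 of 23 higher, 1 lower, adjusted p = 2.1e-07, estimated 0.086) rose, with C1qc 3.73-fold higher (1.90 ± 0.09) and Hmox1 3.44-fold higher (1.78 ± 0.07). Neutrophil markers were higher beside them (5 of 6 higher, 1 lower, adjusted p = 0.0049, estimated 0.084). Lcn2 was 21.3-fold higher (4.41 ± 0.26), as was the acute phase gene Saa3, 12.1-fold higher (3.59 ± 0.21). Stromal markers were lower in KO (14 of 21 lower, 1 higher, adjusted p = 5.7e-05, estimated 0.095). Collagen Col3a1 was 3.46-fold lower (-1.79 ± 0.11) and Sparc 2.01-fold lower (-1.01 ± 0.07).

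The p53 list was higher in 6-month KO (20 of 34 higher, 9 lower, 20 and 10 adjusted over the list alone, adjusted p = 0.027, estimated 0.063). Its members went both ways: Cdkn1a was 2.62-fold higher (1.39 ± 0.05) and Mdm2, the p53 ubiquitin ligase, 1.56-fold higher (0.65 ± 0.05), while the apoptosis effector Pmaip1 was 4.24-fold lower (-2.09 ± 0.08). Cdkn2a was 2.61-fold higher (1.39 ± 0.11), at 37.7 ± 1.68 CPM against 14.4 ± 0.715 CPM. Cell cycle genes rose (30 of 39 higher, 4 lower, adjusted p = 2.4e-06, estimated 0.084). Rrm2, which makes nucleotides for DNA synthesis, was 2.04-fold higher (1.03 ± 0.06) and the replication clamp Pcna 1.99-fold higher (0.99 ± 0.06). Telomere maintenance genes did not pass as a list (11 of 26 higher, 7 lower, adjusted p = 0.46). Mitochondrial transcripts fell (12 of 13 lower, 1 higher, adjusted p = 9.8e-08, estimated 0.070). The transcript mt-Cytb was 2.54-fold lower (-1.34 ± 0.05). Nuclear genes of oxidative phosphorylation fell too (35 of 48 lower, 8 higher, 36 and 8 adjusted over the list alone, adjusted p = 1.2e-05, estimated 0.48). Succinate dehydrogenase Sdha was 2.02-fold lower (-1.01 ± 0.04). Lists that did not pass were glycolysis (11 of 31 higher, 11 lower, adjusted p = 0.78), cholesterol synthesis (9 of 27 lower, 8 higher, 10 and 8 adjusted over the list alone, adjusted p = 0.32), the unfolded protein response (11 of 25 higher, 6 lower, adjusted p = 0.32), B and plasma cell markers (2 of 6 higher, 1 lower, adjusted p = 0.93) and endothelial markers (2 of 8 higher, 1 lower, adjusted p = 0.46). Of 4 measured T and NK markers 2 were higher and 2 lower, and of 2 mast and basophil markers none passed. Heat shock and immediate early genes (11 of 22 higher, 2 lower, adjusted p = 0.037, estimated 0.44) and histone genes (17 of 34 lower, 7 higher, adjusted p = 0.043, estimated 0.23) passed, but not without KO replicate 3 for the first (adjusted p = 0.054) and not without WT replicate 2 (adjusted p = 0.062) or KO replicate 2 (adjusted p = 0.053) for the second.

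Between KO and WT at 6 months 9179 genes passed, 4669 higher and 4510 lower. With set 519 as KO, the log2 fold change turned past the threshold to 0.53 for Mmp9 and 0.66 for Calcr, and for Itgb3, Oscar and Acp5. Calls were lost for Ctsk (-0.16, adjusted p = 0.075), Saa3 (0.53), Rrm2, Dcstamp and Steap4. The resorption median was 0.23 against -1.39, and that of cell cycle genes -0.56 (adjusted p = 1.9e-12). V-ATPase genes turned too, fusion genes passed as higher and telomere genes as lower, and nuclear oxidative phosphorylation, heat shock, histone, SASP and neutrophil lists lost their calls. The interferon-stimulated list was higher in KO with that set too, with a median of 1.08 (camera adjusted p = 7.9e-13 at the preset correlation).

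**Figure D2:**
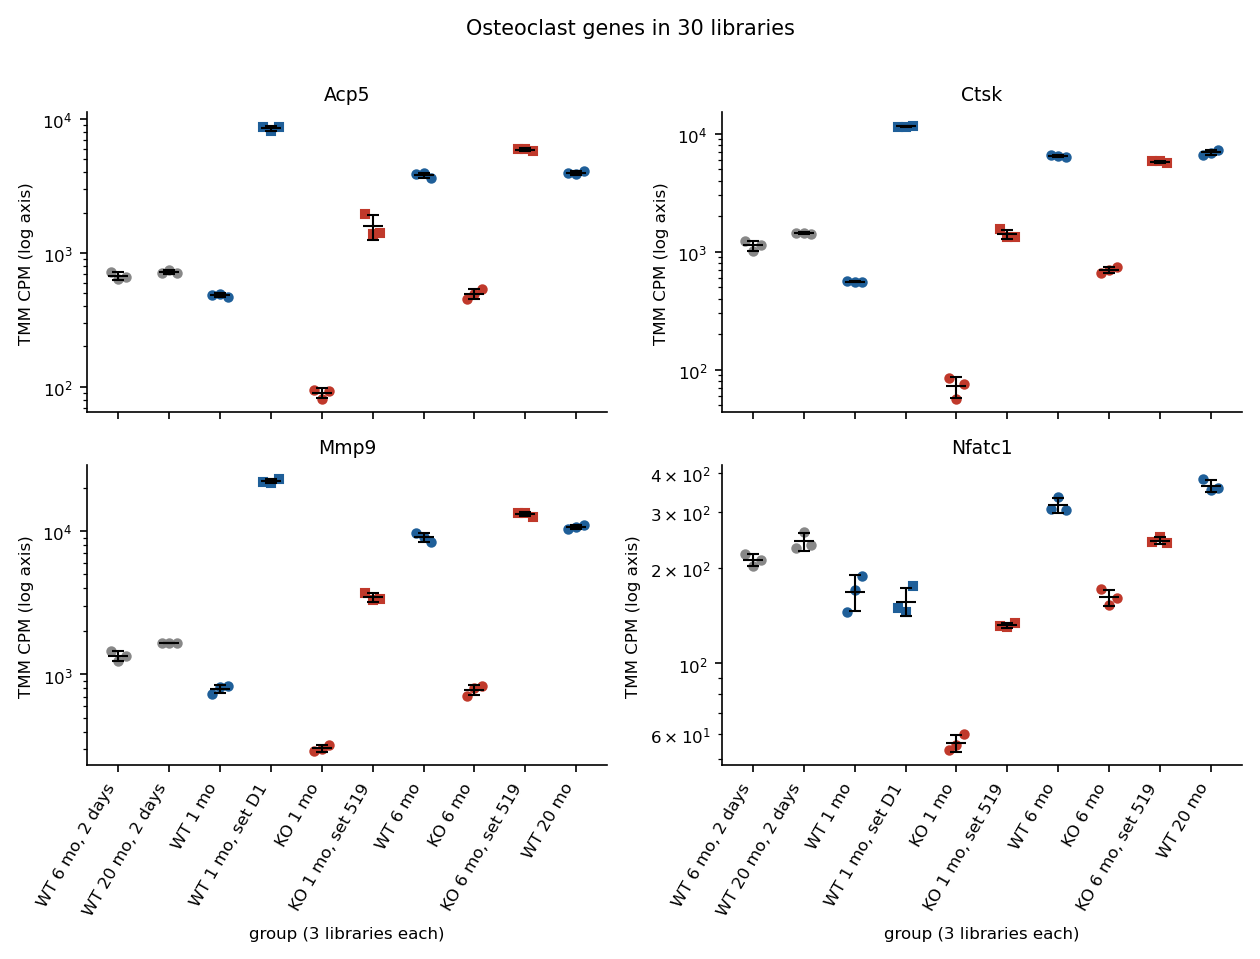
TMM-scaled CPM (log axis) of Acp5, Ctsk, Mmp9 and Nfatc1 in each library, by group, with the mean and SD of the 3 libraries. In unprefixed KO all 4 genes lie below WT of the same age, while in set 519 Mmp9 lies above the unprefixed WT libraries of the same age.

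**Figure D3:**
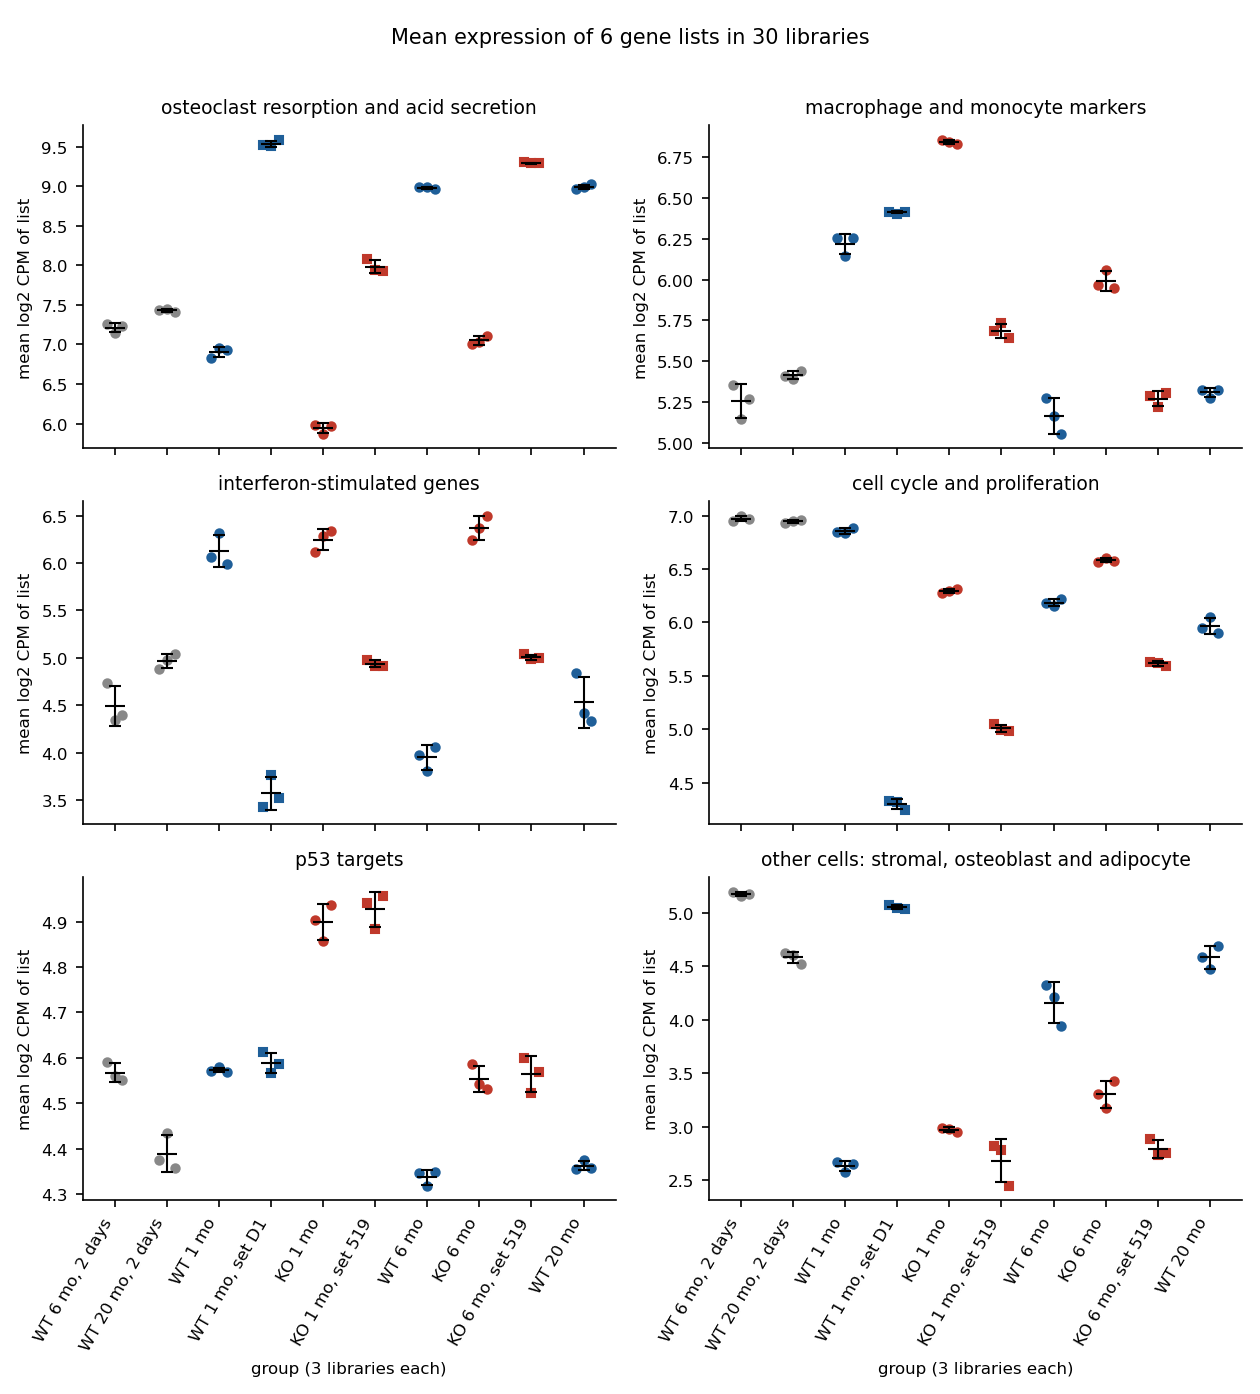
Mean log2 CPM over the members of 6 gene lists in each library, by group, with the group mean. The interferon-stimulated list is lower in 6-month than in unprefixed 1-month WT, but not lower than in set D1, and higher in unprefixed 6-month KO than in 6-month WT.

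The interaction of genotype and age asked whether the KO effect differs between 1 and 6 months. All 40 interferon-stimulated genes had a higher KO effect at 6 months (adjusted p = 1.6e-25, estimated 0.073). Irf7 shifted up by 12.8-fold (3.68 ± 0.19) and Ly6a by 24.2-fold (4.60 ± 0.15). Cell cycle genes shifted the same way (39 of 39 higher, 0 lower, adjusted p = 8.2e-22). Cdc20 shifted up by 2.92-fold (1.55 ± 0.10) and Rrm2 by 2.84-fold (1.51 ± 0.08). The resorption list shifted down (15 of 20 lower, 0 higher, 18 and 0 adjusted over the list alone, adjusted p = 5.6e-11). Mmp9 shifted down by 4.47-fold (-2.16 ± 0.09) and Itgb3 by 5.47-fold (-2.45 ± 0.11). Mitochondrial transcripts (12 of 13 lower, 1 higher, adjusted p = 1.5e-07, estimated 0.078) and stromal markers (14 of 21 lower, 0 higher, adjusted p = 1.2e-06, estimated 0.073) shifted down too, mt-Co1 by 2.0-fold (-1.0 ± 0.05) and collagen Col6a1 by 7.49-fold (-2.90 ± 0.18). Telomere (15 of 26 higher, 3 lower, adjusted p = 0.013, estimated 0.054) and DNA repair genes (17 of 31 higher, 0 lower, 19 and 0 adjusted over the list alone, adjusted p = 0.0041, estimated 0.073) shifted up. Akr1c18 shifted down by 31.3-fold (-4.97 ± 0.17). In total 7443 genes passed, 4142 with a higher KO effect at 6 months and 3301 with a lower one. With set D1 as 1-month WT, the median shift was -0.23 for interferon-stimulated, -1.63 for cell cycle and 1.24 for resorption genes against 2.12, 0.95 and -0.69. The interferon list and Irf7 lost their calls with it, and the other lists and genes named here turned past the threshold, except Ly6a. With set 519 as KO of both ages the medians were 2.18, 1.28 and -0.34.

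Age in WT was followed in unprefixed multinucleated cultures. From 1 to 6 months, resorption genes rose, from a 1-month group whose Ctsk and Mmp9 lay below those of the 2-day cultures. With set D1, the other 1-month WT group, the median turned past the threshold to -0.52 against 1.64, and that of interferon-stimulated genes to 0.46 against -2.21. V-ATPase, cell cycle, mitochondrial and stromal genes turned too, as did each gene named below but Bst2 and Ccl2, which lost their calls, and Tlr2. Calcr was 126-fold higher (6.97 ± 0.15) at 6 months, Mmp9 11.4-fold higher (3.51 ± 0.07), at 9054 ± 642 CPM against 793 ± 51.4 CPM, and Itgb3 10.7-fold higher (3.41 ± 0.07). Of the resorption list 19 of 20 measured members rose and 0 fell (adjusted p = 6.4e-17). V-ATPase subunits rose (13 of 18 higher, 3 lower, adjusted p = 4.3e-05, estimated 0.11). All 40 interferon-stimulated genes fell (adjusted p = 1.3e-21, estimated 0.077). Irf7 was 9.84-fold lower (-3.30 ± 0.15) and the antiviral protein tetherin, Bst2, 5.33-fold lower (-2.41 ± 0.11). Macrophage markers (19 of 24 lower, 1 higher, adjusted p = 6.9e-08), inflammatory and SASP genes (23 of 32 lower, 3 higher, adjusted p = 3.5e-07), NRF2 genes (20 of 23 lower, 1 higher, adjusted p = 6.9e-08, estimated 0.077) and cell cycle genes (35 of 39 lower, 0 higher, 35 and 1 adjusted over the list alone, adjusted p = 1.8e-12) fell, with Ccl2 8.20-fold lower (-3.04 ± 0.13), the receptor Tlr2 4.47-fold lower (-2.16 ± 0.07) and Rrm2 2.37-fold lower (-1.25 ± 0.06). The p53 list fell (21 of 34 lower, 8 higher, 22 and 8 adjusted over the list alone, adjusted p = 0.014). Mitochondrial transcripts rose (12 of 13 higher, 1 lower, adjusted p = 2.9e-06, estimated 0.088). Neutrophil markers fell (5 of 6 lower, 0 higher, adjusted p = 0.0049, estimated 0.077) and stromal markers rose (18 of 21 higher, 0 lower, adjusted p = 1.3e-08). Dcn was 6.55-fold higher (2.71 ± 0.12) and Pdgfrb 4.52-fold higher (2.18 ± 0.10). In total 9743 genes passed, 4772 higher and 4971 lower.

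From 6 to 20 months fewer genes passed in WT. Interferon-stimulated genes rose (31 of 40 higher, 0 lower, 32 and 0 adjusted over the list alone, adjusted p = 4.2e-23, estimated 0.058). Irf7 was 2.14-fold higher (1.10 ± 0.15) and Slfn5 1.62-fold higher (0.70 ± 0.10). The MHC class II list passed (4 of 12 higher, 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.014). The invariant chain Cd74 was 2.09-fold higher (1.06 ± 0.10) and H2-Ab1 2.98-fold higher (1.57 ± 0.17). Glycolysis and hypoxia genes rose (24 of 31 higher, 0 lower, 26 and 0 adjusted over the list alone, adjusted p = 1.9e-18). The collagen hydroxylase P4ha2 was 2.15-fold higher (1.10 ± 0.10) and Vegfa 1.68-fold higher (0.75 ± 0.10). Coupling factors rose (6 of 16 higher, 0 lower, 8 and 1 adjusted over the list alone, adjusted p = 0.0052). The NRF2 (16 of 23 lower, 0 higher, 19 and 0 adjusted over the list alone, adjusted p = 2.3e-18), cell cycle (24 of 39 lower, 0 higher, 31 and 0 adjusted over the list alone, adjusted p = 2.0e-14) and DNA repair lists (5 of 31 lower, 0 higher, adjusted p = 0.0035) fell. Hmox1 was 1.63-fold lower (-0.71 ± 0.07) and the replication licensing factor Mcm5 1.29-fold lower (-0.37 ± 0.06). The inflammatory and SASP list fell (11 of 32 lower, 5 higher, 11 and 6 adjusted over the list alone, adjusted p = 0.014, estimated 0.37). Ccl7 was 2.53-fold lower (-1.34 ± 0.23). The resorption list did not pass (3 of 20 higher, 1 lower, 3 and 3 adjusted over the list alone, adjusted p = 0.99). The corneodesmosin gene Cdsn was 4.73-fold higher (2.24 ± 0.24), the water channel Aqp1 3.71-fold higher (1.89 ± 0.20) and the scavenger receptor Marco 2.79-fold lower (-1.48 ± 0.13). Stromal markers rose (11 of 21 higher, 1 lower, 13 and 1 adjusted over the list alone, adjusted p = 3.1e-09). Col1a1 was 2.52-fold higher (1.34 ± 0.09) but Dcn 3.63-fold lower (-1.86 ± 0.11). In total 2188 genes passed, 1132 higher and 1056 lower, but 33.3% were higher with the length trend removed. The count was 1378 without WT_6M_multinucleated replicate 3, 1448 without its replicate 4, 1444 without WT_20M_multinucleated replicate 1 and 1343 without its replicate 4.

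In 20-month against unprefixed 1-month WT, whose Ctsk and Mmp9 lay below those of the 2-day cultures, resorption genes rose. Against set D1 the median turned past the threshold to -0.50 against 1.85. V-ATPase genes turned too, as did each gene named below but Nfatc1, and Kazn and Vegfa, which lost their calls with the glycolysis list. Calcr was 124-fold higher (6.96 ± 0.15), Mmp9 13.5-fold higher (3.75 ± 0.07), Ctsk 12.4-fold higher (3.63 ± 0.09), at 6928 ± 359 CPM against 559 ± 8.61 CPM, and Acp5 8.22-fold higher (3.04 ± 0.09). Dcstamp was 3.28-fold higher (1.71 ± 0.07) and Nfatc1 2.16-fold higher (1.11 ± 0.07). Of the resorption list 19 of 20 measured members rose and 0 fell (adjusted p = 3.1e-14). V-ATPase subunits rose (12 of 18 higher, 3 lower, adjusted p = 8.0e-04, estimated 0.20). The chloride channel protein Clic5 was 33.8-fold higher (5.08 ± 0.19), the junction protein Kazn 32.8-fold higher (5.04 ± 0.22) and the integrin Itga2 29.8-fold higher (4.90 ± 0.22). RANK signalling genes had a median of -0.06 while the camera direction was up (11 of 25 lower, 10 higher, 12 and 10 adjusted over the list alone, adjusted p = 0.85). Glycolysis and hypoxia genes rose (19 of 31 higher, 5 lower, adjusted p = 0.0014, estimated 0.43). Vegfa was 5.09-fold higher (2.35 ± 0.11) and the pyruvate dehydrogenase kinase Pdk1 2.39-fold higher (1.26 ± 0.06).

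Inflammatory, macrophage and growth genes were lower at 20 months than in unprefixed 1-month WT. Against set D1 the cell cycle (median 1.76), interferon (0.97 against -1.61), telomere and stromal lists turned past the threshold, as did Rrm2, Pcna, Pmaip1 and Col1a1, while the inhibitor list, Hmga1, Bst2 and Cdkn1b lost their calls. All 40 interferon-stimulated genes fell (adjusted p = 3.0e-14, estimated 0.15). Bst2 was 4.96-fold lower (-2.31 ± 0.11). Inflammatory and SASP genes fell (27 of 32 lower, 3 higher, adjusted p = 2.7e-07). Ccl2 was 19.2-fold lower (-4.27 ± 0.14) and Ccl7 17.2-fold lower (-4.11 ± 0.20), and the osteoprotegerin gene Tnfrsf11b was 8.56-fold higher (3.10 ± 0.16). Macrophage markers fell (16 of 24 lower, 3 higher, adjusted p = 3.6e-05). Marco was 33.9-fold lower (-5.08 ± 0.13) and Lyz2 3.71-fold lower (-1.89 ± 0.05). Lysosomal genes (17 of 26 lower, 4 higher, adjusted p = 2.4e-04, estimated 0.32) and NRF2 genes (22 of 23 lower, 0 higher, adjusted p = 4.9e-11) fell as well. The cathepsin Ctsl was 4.19-fold lower (-2.07 ± 0.07) and Hmox1 5.22-fold lower (-2.38 ± 0.07). Cell cycle genes fell (36 of 39 lower, 0 higher, 36 and 1 adjusted over the list alone, adjusted p = 2.6e-14). Rrm2 was 2.87-fold lower (-1.52 ± 0.06) and Pcna 2.67-fold lower (-1.41 ± 0.06). The p53 list fell (21 of 34 lower, 9 higher, adjusted p = 0.031, estimated 0.063). Cdkn1a was 2.94-fold lower (-1.55 ± 0.05) but Pmaip1 3.91-fold higher (1.97 ± 0.08). Cell cycle inhibitors and senescence genes fell as a list (9 of 15 lower, 3 higher, 9 and 4 adjusted over the list alone, adjusted p = 0.031, estimated 0.15). Cdkn2a was 3.80-fold lower (-1.92 ± 0.12) and the chromatin protein Hmga1 4.23-fold lower (-2.08 ± 0.08) but Cdkn1b 3.08-fold higher (1.62 ± 0.08). Telomere genes fell (15 of 26 lower, 5 higher, adjusted p = 0.041, estimated 0.081). Stromal markers rose (19 of 21 higher, 0 lower, adjusted p = 9.0e-10). Col1a1 was 6.88-fold higher (2.78 ± 0.09). Neutrophil markers fell (5 of 6 lower, 0 higher, adjusted p = 0.0042, estimated 0.081). In total 10497 genes passed, 5234 higher and 5263 lower.

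In KO, age was followed in unprefixed cultures and in set 519, 6 against 1 month. Both 1-month sets shared features with no other group (last section), so age was not told apart from strain or donor. Unprefixed KO lay below 2-day WT in Ctsk at both ages. Resorption and fusion genes rose in both. In unprefixed KO, Ctsk was 9.65-fold higher (3.27 ± 0.09), Acp5 5.47-fold higher (2.45 ± 0.09), Dcstamp 4.98-fold higher (2.32 ± 0.07) and Nfatc1 2.88-fold higher (1.53 ± 0.08). In set 519, Mmp9 was 3.79-fold higher (1.92 ± 0.06), Itgb3 3.12-fold higher (1.64 ± 0.06), Ctsk 4.09-fold higher (2.03 ± 0.08) and Dcstamp 4.20-fold higher (2.07 ± 0.07). The resorption list rose in the unprefixed set (17 of 20 higher, 2 lower, adjusted p = 6.8e-16) and in set 519 (19 of 20 higher, 0 lower, adjusted p = 1.7e-20), as did the fusion list (10 of 15 higher, 4 lower in each, adjusted p = 0.0020, then 0.013, estimated 0.079). RANK signalling genes rose in the unprefixed set (13 of 25 higher, 6 lower, adjusted p = 2.5e-04, estimated 0.093). The p53 list fell in both sets (20 of 34 lower, 2 higher, adjusted p = 3.5e-07, then 18 of 34 lower, 1 higher, 19 and 1 adjusted over the list alone, adjusted p = 1.9e-06). Plk2 was 2.42-fold lower (-1.28 ± 0.06) and Phlda3 2.38-fold lower (-1.25 ± 0.10) in unprefixed KO, and Phlda3 2.28-fold lower (-1.19 ± 0.12) and Cdkn1a 1.53-fold lower (-0.61 ± 0.05) in set 519. Cell cycle genes rose in both (27 of 39 higher, 1 lower, 28 and 2 adjusted over the list alone, adjusted p = 7.5e-08, then 36 of 39 higher, 1 lower, adjusted p = 2.3e-17). Ccnb1 was 1.47-fold higher (0.55 ± 0.05) and Top2a 1.85-fold higher (0.89 ± 0.07).

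Macrophage and NRF2 genes were lower at 6 months in both KO sets. Macrophage markers fell (19 of 24 lower, 1 higher, adjusted p = 1.3e-12 in the unprefixed set, 11 of 24 lower, 3 higher, 11 and 4 adjusted over the list alone, adjusted p = 5.8e-04, estimated 0.070 in set 519). Marco was 10.7-fold lower (-3.42 ± 0.12) in unprefixed KO. NRF2 genes fell (18 of 23 lower, 0 higher, 19 and 0 adjusted over the list alone, adjusted p = 2.2e-11, then 15 of 23 lower, 2 higher, adjusted p = 7.1e-08, estimated 0.086). Hmox1 was 2.18-fold lower (-1.13 ± 0.07) in the unprefixed set. The lipid carrier Apoe of the LXR list was 3.60-fold lower (-1.85 ± 0.15) and, in set 519, 3.66-fold lower (-1.87 ± 0.15). Nuclear genes of oxidative phosphorylation rose in set 519 (45 of 48 higher, 0 lower, adjusted p = 2.1e-17, estimated 0.15), where Sdha was 1.89-fold higher (0.92 ± 0.04), and did not pass in the unprefixed set (11 of 48 higher, 6 lower, adjusted p = 0.69). Cpne8, a calcium-dependent membrane-binding protein, was 14.4-fold higher (3.85 ± 0.10) in unprefixed KO and 6.29-fold higher (2.65 ± 0.11) in set 519, and Sel1l3 was 6.54-fold lower (-2.71 ± 0.10) and 7.43-fold lower (-2.89 ± 0.13). The Y-linked translation factor Eif2s3y was 3.19-fold higher (1.67 ± 0.06) at 6 months in the first and 3.95-fold higher (1.98 ± 0.08) in the second. The sex-linked list passed in the unprefixed set (2 of 5 higher, 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.029, estimated 0.12). Stromal markers rose (9 of 21 higher, 1 lower, 10 and 2 adjusted over the list alone, adjusted p = 0.0081, estimated 0.27) and neutrophil markers fell (5 of 6 lower, 0 higher, adjusted p = 0.0077, estimated 0.070) in unprefixed KO. In total 5742 genes passed in unprefixed KO, 3011 higher and 2731 lower. In set 519 4970 passed, 2944 higher and 2026 lower, but 48.0% were higher with RLE and 48.4% with DESeq2.

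The step from 2 days of cytokines to multinucleated cells was measured in WT of 6 and 20 months. At 6 months, all 20 measured resorption genes rose (adjusted p = 1.2e-22). Calcr was 35.8-fold higher (5.16 ± 0.13), Mmp9 6.72-fold higher (2.75 ± 0.07), at 9054 ± 642 CPM against 1347 ± 102 CPM, Ctsk 5.72-fold higher (2.52 ± 0.08), Acp5 5.67-fold higher (2.50 ± 0.08), Itgb3 4.10-fold higher (2.03 ± 0.07) and Oscar 9.96-fold higher (3.32 ± 0.11). Fusion genes rose (9 of 15 higher, 3 lower, adjusted p = 0.0010). Dcstamp was 3.39-fold higher (1.76 ± 0.07). RANK signalling genes rose (17 of 25 higher, 3 lower, adjusted p = 4.8e-04, estimated 0.13). Nfatc1 was 1.49-fold higher (0.57 ± 0.07). V-ATPase subunits rose (16 of 18 higher, 0 lower, adjusted p = 1.5e-15). Atp6v1a was 2.63-fold higher (1.39 ± 0.05) and Atp6v0d2 3.30-fold higher (1.72 ± 0.06). Nuclear (43 of 48 higher, 0 lower, adjusted p = 2.2e-15, estimated 0.18) and mitochondrial (12 of 13 higher, 0 lower, 13 and 0 adjusted over the list alone, adjusted p = 1.2e-06, estimated 0.089) genes of oxidative phosphorylation rose, with Sdha 1.87-fold higher (0.90 ± 0.04) and mt-Co1 1.70-fold higher (0.77 ± 0.04). Histone genes rose too (18 of 34 higher, 8 lower, 19 and 8 adjusted over the list alone, adjusted p = 0.011, estimated 0.13). Hist2h2be was 4.74-fold higher (2.24 ± 0.09). The protease Corin was 26.1-fold higher (4.71 ± 0.18) and Steap4 21.6-fold higher (4.43 ± 0.14).

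Growth and stress genes fell over the same step. All 39 cell cycle genes fell (adjusted p = 6.6e-22). Rrm2 was 2.29-fold lower (-1.20 ± 0.06) and the spindle factor Tpx2 1.84-fold lower (-0.88 ± 0.05). DNA repair genes fell (20 of 31 lower, 1 higher, 20 and 2 adjusted over the list alone, adjusted p = 2.1e-04). The p53 list fell (20 of 34 lower, 6 higher, adjusted p = 0.011). Cdkn1a was 1.38-fold lower (-0.47 ± 0.05) but Pmaip1 2.73-fold higher (1.45 ± 0.08), and Cdkn2a was at 1.06-fold higher (0.09 ± 0.12, adjusted p = 0.58). Unfolded protein and integrated stress response genes fell (16 of 25 lower, 3 higher, adjusted p = 4.7e-04, estimated 0.21). The serine synthesis enzyme Phgdh was 5.02-fold lower (-2.33 ± 0.12). Inflammatory and SASP genes fell (22 of 32 lower, 2 higher, 23 and 3 adjusted over the list alone, adjusted p = 9.8e-06, estimated 0.072). The prostaglandin synthase Ptgs2 was 8.93-fold lower (-3.16 ± 0.12). Interferon-stimulated genes (28 of 40 lower, 0 higher, 30 and 0 adjusted over the list alone, adjusted p = 3.5e-04, estimated 0.47) and heat shock and immediate early genes fell (11 of 22 lower, 1 higher, 13 and 1 adjusted over the list alone, adjusted p = 0.0011, estimated 0.21). Egr1 was 3.60-fold lower (-1.85 ± 0.12). The caveolar protein Cavin2 was 20.7-fold lower (-4.37 ± 0.20), Ankrd1 20.0-fold lower (-4.32 ± 0.20), endothelin Edn1 16.5-fold lower (-4.05 ± 0.20) and the lectin Siglecg 16.4-fold lower (-4.03 ± 0.16). Stromal markers fell beside these (14 of 21 lower, 3 higher, 15 and 3 adjusted over the list alone, adjusted p = 1.6e-05, estimated 0.089). The smooth muscle actin Acta2 was 9.07-fold lower (-3.18 ± 0.09) and Sparc 2.95-fold lower (-1.56 ± 0.07). In total 7781 genes passed, 3582 higher and 4199 lower.

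At 20 months resorption genes likewise rose in the step to multinucleated cells (19 of 20 higher, 0 lower, adjusted p = 3.6e-20). Mmp9 was 6.46-fold higher (2.69 ± 0.07), Calcr 14.2-fold higher (3.83 ± 0.11), Acp5 5.52-fold higher (2.46 ± 0.08) and Oscar 8.33-fold higher (3.06 ± 0.11), and Corin was 26.3-fold higher (4.72 ± 0.17). Fusion (9 of 15 higher, 5 lower, adjusted p = 0.013, estimated 0.11), RANK signalling (15 of 25 higher, 3 lower, adjusted p = 0.0010, estimated 0.16) and V-ATPase genes rose (17 of 18 higher, 0 lower, adjusted p = 3.4e-14). Dcstamp was 2.50-fold higher (1.32 ± 0.07) and the proton pump subunit Tcirg1 2.42-fold higher (1.28 ± 0.05). Glycolysis and hypoxia genes rose (26 of 31 higher, 1 lower, 27 and 1 adjusted over the list alone, adjusted p = 2.0e-09, estimated 0.16). Aldolase Aldoc was 2.86-fold higher (1.51 ± 0.07) and Pdk1 1.94-fold higher (0.96 ± 0.06). Nuclear genes of oxidative phosphorylation rose (44 of 48 higher, 0 lower, 45 and 0 adjusted over the list alone, adjusted p = 2.1e-15, estimated 0.19). All 39 cell cycle genes fell (adjusted p = 1.8e-27). Rrm2 was 2.83-fold lower (-1.50 ± 0.06). Telomere (13 of 26 lower, 5 higher, 14 and 5 adjusted over the list alone, adjusted p = 0.013), DNA repair (22 of 31 lower, 1 higher, 24 and 1 adjusted over the list alone, adjusted p = 6.2e-08), stress response (18 of 25 lower, 4 higher, adjusted p = 1.5e-05, estimated 0.16) and inflammatory genes fell (17 of 32 lower, 5 higher, 18 and 5 adjusted over the list alone, adjusted p = 6.0e-04, estimated 0.16). Dkc1 was 1.77-fold lower (-0.82 ± 0.06), the serine synthesis enzyme Psat1 2.46-fold lower (-1.30 ± 0.07), Ccl7 6.93-fold lower (-2.79 ± 0.21) and Ccl2 4.99-fold lower (-2.32 ± 0.14). Stromal markers did not pass (9 of 21 lower, 6 higher, adjusted p = 0.61). In total 8010 genes passed, 3895 higher and 4115 lower.

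In 2-day cultures, 20-month against 6-month WT, interferon-stimulated genes rose (27 of 40 higher, 0 lower, adjusted p = 3.5e-17, estimated 0.17). Slfn5 was 1.80-fold higher (0.85 ± 0.10). MHC class II genes rose (4 of 12 higher, 0 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.025, estimated 0.079). Cd74 was 1.72-fold higher (0.78 ± 0.13). Resorption genes rose (9 of 20 higher, 0 lower, adjusted p = 5.1e-04, estimated 0.20). Car2 was 1.86-fold higher (0.89 ± 0.09). Inflammatory and SASP genes fell (17 of 32 lower, 1 higher, 23 and 2 adjusted over the list alone, adjusted p = 1.4e-08, estimated 0.072). Targets of p53 (10 of 34 lower, 2 higher, 11 and 2 adjusted over the list alone, adjusted p = 0.021, estimated 0.072) and NRF2 genes (13 of 23 lower, 0 higher, 15 and 1 adjusted over the list alone, adjusted p = 4.6e-10, estimated 0.079) fell too. Hmox1 was 1.89-fold lower (-0.92 ± 0.07). Stromal markers fell beside them (11 of 21 lower, 0 higher, 15 and 0 adjusted over the list alone, adjusted p = 6.2e-08, estimated 0.072). Acta2 was 2.35-fold lower (-1.24 ± 0.09). The growth factor binding protein Igfbp2 was 11-fold lower (-3.45 ± 0.26), haptoglobin Hp 6.05-fold lower (-2.60 ± 0.26), the kinase Fgr 2.68-fold higher (1.42 ± 0.08) and the integrin Itgax 2.52-fold higher (1.33 ± 0.12). In total 2880 genes passed, 1145 higher and 1735 lower, but 58.6% were higher with the length trend removed. The count was 1739 without WT_6M_2day replicate 2 and 1911 without WT_20M_2day replicate 1.

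The interaction of stage and age asked whether the step to multinucleated cells differs between 6-month and 20-month WT. Stromal markers shifted up at 20 months (12 of 21 higher, 0 lower, 14 and 0 adjusted over the list alone, adjusted p = 1.3e-16). Acta2 shifted by 3.59-fold (1.85 ± 0.12) and collagen Col1a2 by 2.45-fold (1.29 ± 0.10). Glycolysis and hypoxia genes shifted up (20 of 31 higher, 0 lower, 27 and 0 adjusted over the list alone, adjusted p = 4.3e-17, estimated 0.067). P4ha2 shifted by 2.48-fold (1.31 ± 0.14) and Vegfa by 2.28-fold (1.19 ± 0.14). Coupling factors shifted up (6 of 16 higher, 1 lower, 9 and 1 adjusted over the list alone, adjusted p = 1.5e-04). The growth factor Csf1 shifted by 3.28-fold (1.71 ± 0.10). Heat shock and immediate early genes shifted up (9 of 22 higher, 1 lower, 9 and 3 adjusted over the list alone, adjusted p = 0.0050, estimated 0.39). Egr1 shifted by 3.13-fold (1.65 ± 0.17). Resorption genes shifted down (7 of 20 lower, 2 higher, adjusted p = 0.0058, estimated 0.39). Calcr shifted down by 2.51-fold (-1.33 ± 0.20) and Car2 by 1.75-fold (-0.81 ± 0.12). Cell cycle genes shifted down as well (13 of 39 lower, 0 higher, 17 and 0 adjusted over the list alone, adjusted p = 8.8e-08, estimated 0.068), Top2a by 1.34-fold (-0.43 ± 0.09). In total 1896 genes passed, 1152 with a higher and 744 with a lower effect at 20 months, and the count was 2868, 48.5% of them higher, with only the compared groups in the fit, and 3154, 32.2% higher, with the length trend removed.

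Comparisons that share no library were set against each other across all 15310 genes. KO vs WT at 6 months ran opposite to WT at 20 vs 1 month: Spearman's rho was -0.79, and 3.08% of the 7572 genes called in both had the same direction. Genes higher in both numbered 109 and lower in both 124, where independent lists would share 1596 and 1550. With set D1 as 1-month WT rho was 0.039. The KO effects at 1 and 6 months were related at 0.16, with 66.9% of 4478 shared calls in the same direction (1676 higher and 1321 lower in both, against 964 and 936 by chance), and at 0.71 with set D1 as 1-month WT. The step to multinucleated cells at 6 and 20 months was related at 0.75, with 98.5% of 5891 shared calls in the same direction (2777 higher and 3027 lower, against 911 and 1129). KO 6 vs 1 month in the unprefixed set and in set 519 was related at 0.47, with 92.0% of 3045 (1591 higher and 1210 lower, against 579 and 361). KO vs WT at 1 month and WT at 20 vs 6 months were related at 0.19, with 74.0% of 1344 (476 higher and 518 lower, against 234 and 219), and at -0.30 with set D1 as 1-month WT. WT at 20 vs 6 months in multinucleated and in 2-day cultures was related at 0.08, with 57.3% of 857 (234 higher and 257 lower, against 84.7 and 119.7), but 315 genes were higher in multinucleated and lower in 2-day cultures, against 128.3.

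Title sets of the same genotype, age and stage were compared last. Set 519 KO held more resorption gene RNA than unprefixed KO at both ages. At 1 month Ctsk was 19.4-fold higher (4.28 ± 0.09) in set 519, Mmp9 11.3-fold higher (3.50 ± 0.07), Itgb3 12.8-fold higher (3.67 ± 0.08) and Oscar 41.0-fold higher (5.36 ± 0.18). The resorption list rose (18 of 20 higher, 0 lower, adjusted p = 1.5e-19). At 6 months Calcr was 109-fold higher (6.76 ± 0.13), Mmp9 16.7-fold higher (4.07 ± 0.07), Itgb3 20.4-fold higher (4.35 ± 0.07) and the fusion-related lectin Siglec15 13.4-fold higher (3.74 ± 0.14). All 20 members rose (adjusted p = 2.7e-26). Inflammatory and SASP genes were lower in set 519 (29 of 32 lower, 0 higher, 30 and 0 adjusted over the list alone, adjusted p = 4.4e-14 at 1 month, 26 of 32 lower, 0 higher, 27 and 0 adjusted over the list alone, adjusted p = 2.4e-12 at 6 months). Saa3 was 41.6-fold lower (-5.38 ± 0.25) and Ccl2 11.5-fold lower (-3.52 ± 0.14) at 1 month and Ccl2 5.66-fold lower (-2.50 ± 0.13) at 6 months. All 40 interferon-stimulated genes were lower (adjusted p = 4.8e-14, estimated 0.15 at 1 month, adjusted p = 1.9e-17, estimated 0.10 at 6 months). Irf7 was 4.0-fold lower (-2.0 ± 0.15) at 1 month and Zbp1 4.68-fold lower (-2.23 ± 0.15) at 6 months. All 39 cell cycle genes were lower (adjusted p = 3.0e-29, then adjusted p = 1.3e-25). Mcm6 was 2.33-fold lower (-1.22 ± 0.05) at 1 month and Rrm2 2.19-fold lower (-1.13 ± 0.06) at 6 months. Marco was 15.5-fold lower (-3.96 ± 0.12) at 1 month, and Hist1h1c 3.08-fold higher (1.62 ± 0.08) and Fos 2.25-fold lower (-1.17 ± 0.06) at 6 months. Of 15310 genes 7658 passed at 1 month, 3347 higher and 4311 lower, and 7511 at 6 months, 3454 higher and 4057 lower.

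Set D1 and unprefixed 1-month WT differed in more genes than any other pair compared here. On the CPM of the library total, Xist was at least 19396-fold higher in set D1, and Eif2s3y at least 1245-fold, Ddx3y at least 1179-fold and Kdm5d at least 503-fold lower, each against a limit of 3 counts over the group at 0. Mmp9 was 28.1-fold higher (4.81 ± 0.07), Itgb3 21.2-fold higher (4.40 ± 0.07) and the cytokine Lif 9.36-fold higher (3.23 ± 0.11). The resorption list rose (19 of 20 higher, 0 lower, 20 and 0 adjusted over the list alone, adjusted p = 3.9e-14). All 39 cell cycle genes fell (adjusted p = 4.0e-25). Mcm5 was 9.80-fold lower (-3.29 ± 0.06) and Ccnb1 7.18-fold lower (-2.84 ± 0.06). DNA repair genes fell (23 of 31 lower, 1 higher, adjusted p = 1.4e-06). Ribosomal protein genes fell (80 of 81 lower, 0 higher, adjusted p = 1.1e-17, estimated 0.39). Rps18 was 2.61-fold lower (-1.38 ± 0.06). All 40 interferon-stimulated genes fell (adjusted p = 5.9e-16, estimated 0.16). Oas1a was 7.97-fold lower (-3.0 ± 0.11) and Ifi27l2a 29.8-fold lower (-4.90 ± 0.18). Stromal markers rose (17 of 21 higher, 0 lower, 18 and 0 adjusted over the list alone, adjusted p = 6.5e-09). Col1a1 was 10.1-fold higher (3.34 ± 0.09). Erythroid and platelet markers did not pass (4 of 5 higher, 1 lower, adjusted p = 0.20). In total 11399 genes passed, 5748 higher and 5651 lower.

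**Figure D4:**
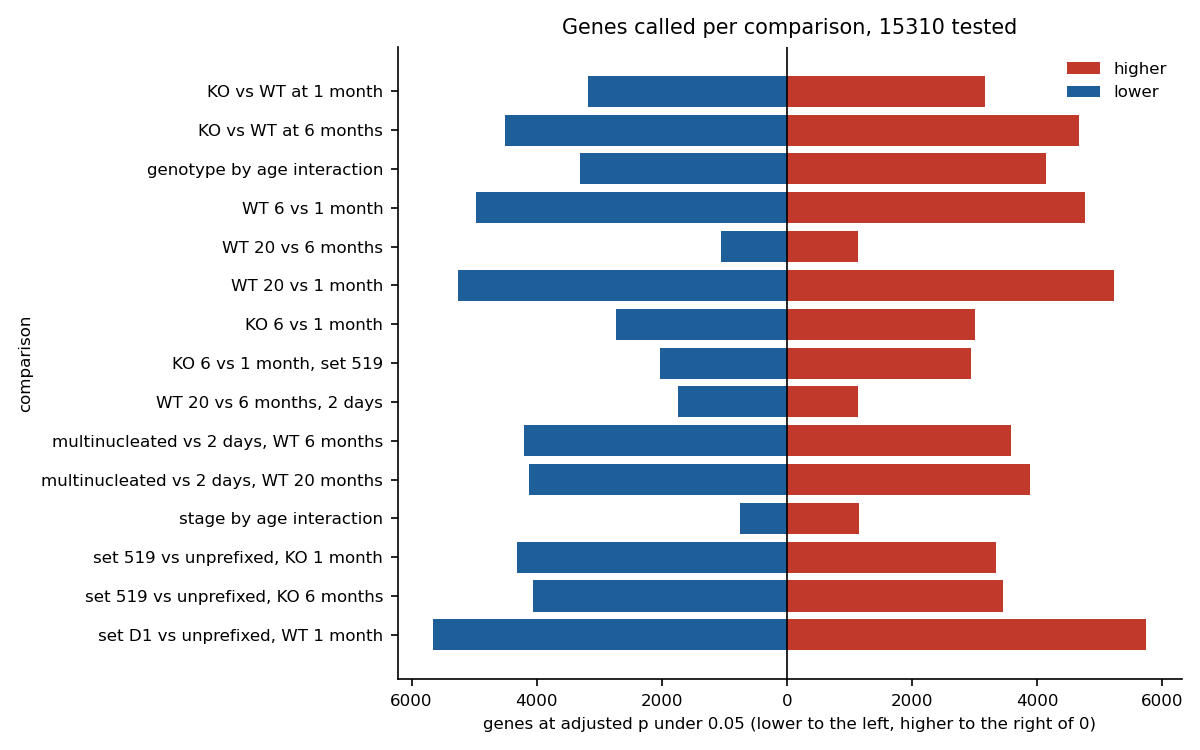
Number of genes with adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg) in each of the 15 comparisons, higher and lower apart. The count runs from 1896 to 11399.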

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

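The tests of stromal dilution, of thinning, of the length trend, with set D1 as 1-month WT, and of the splits for KO vs WT at 1 month and for the interaction of genotype and age were chosen after the results were seen.

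Each difference below is an interaction term that passed, so 2 ages differed in the same contrast. The KO effect differed between 1 and 6 months in 7443 genes. The term passed for the resorption list (camera adjusted p = 5.6e-11) and the cell cycle list (adjusted p = 8.2e-22). On the log2 scale the KO effect was higher at 6 months by 3.68 for Irf7, 4.60 for Ly6a, 1.55 for Cdc20 and 1.51 for Rrm2. It was lower by a difference of -2.16 for Mmp9, -2.45 for Itgb3, -1.0 for mt-Co1, -2.90 for Col6a1 and -4.97 for Akr1c18. Of 40 splits drawn from 200, 2 gave as many genes, the real one included, and the highest other gave 8398. Such splits carry the effect of genotype itself, so the count does not decide on chance. With set D1 as 1-month WT the shift reversed past the threshold for both lists and for each gene named but Ly6a, and Irf7, which lost its call.

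The step to multinucleated cells differed between 6-month and 20-month WT in 1896 genes. The term passed for the coupling factor list (adjusted p = 1.5e-04) and the stromal list (adjusted p = 1.3e-16). The effect was higher at 20 months by 1.85 for Acta2, 1.29 for Col1a2, 1.71 for Csf1, 1.31 for P4ha2, 1.19 for Vegfa and 1.65 for Egr1. It was lower, with differences of -0.81 for Car2, -1.33 for Calcr and -0.43 for Top2a. Of 40 splits drawn from 200, 3 gave as many genes, and the highest other gave 5860. These splits carry the effect of stage itself, so the count does not decide on chance.

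For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave the full count. The real count and the highest other were 6340 and 1785 for KO vs WT at 1 month and 9179 and 0 at 6 months. For WT they were 9743 and 0 (6 vs 1 month), 2188 and 11 (20 vs 6 months), 10497 and 0 (20 vs 1 month) and 2880 and 0 (2-day cultures). For KO with age they were 5742 and 0, and 4970 and 3 in set 519. For the step from 2 days they were 7781 and 0 at 6 months and 8010 and 0 at 20 months. Between title sets they were 7658 and 2532 (KO, 1 month), 7511 and 0 (KO, 6 months) and 11399 and 0 (WT).

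At 1 month resorption genes were lower in unprefixed KO than in unprefixed WT (median -0.60) and higher in set 519 KO (median 0.62). A trend on gene length is argued against as the whole cause (median 0.59 with it removed). Thinning to the lowest total (0.69) keeps expected proportions, so it cannot decide on depth. A difference in how far the cultures had matured is a candidate explanation: outside the osteoclast and V-ATPase lists, changes between title sets correlated across genes with those from 2-day to multinucleated cells, at 0.31, 0.46 and 0.64. Mouse line, batch and culture date are not in the labels and stay open.

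The KO effect at 6 months ran opposite to WT ageing from 1 to 20 months (rho -0.79 across genes), but with set D1 as 1-month WT rho was 0.039, so the pattern rests on unprefixed 1-month WT. A lower share of other cells under more stromal cells would move macrophage and resorption genes alike, but their medians lay 2.28 apart. With the length trend removed the correlation was -0.79. With set 519 as the 6-month KO group it was -0.35. A batch shared by the 1-month and unprefixed 6-month KO cultures may thus contribute and stays open. So does maturity: unprefixed 1-month WT and 6-month KO both lay below 2-day WT in Ctsk and Mmp9. A biological effect of Terc loss, not tested apart from these, stays open.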

How the results depend on the processing

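Thinning, removing the length trend, leaving out both unprefixed 1-month libraries numbered 1, set D1 as 1-month WT and set 519 as KO of both ages were chosen after seeing the data. Recomputed were 513 results: 15 counts of genes, 237 genes, 255 lists and 6 correlations between comparisons. Every reversal, of 61 gene values, 68 list medians and 2 correlations, past the threshold or not, came from the title sets. Under all other alternatives, 3291 gene values kept direction and call and 8 lost the call, and 2813 list values kept both while 273 lost the call. Of those 273, 170 fell to the estimated correlation, which left 85 of 255 lists unchanged. Another 41 fell to a library left out, 32 to thinning, 20 to the length trend, 5 to RLE, 4 to the block and 1 to leaving out the libraries numbered 1. There the 6 correlations kept their sign, but 42 of their values moved by more than the SD over left-out libraries, 36 with a library left out and 6 with genes of mean log2 CPM 3 or more.

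Title sets reversed directions in KO vs WT. Except for resorption genes at 1 month, the cause was not tested. At 1 month, set 519 KO against unprefixed WT gave log2 fold changes of 1.34 for Ctsk, 1.71 for Acp5, 2.12 for Mmp9, 0.51 for Mst1r, 0.095 for Dcstamp, -0.55 for Mmp13 and -3.30 for Lcn2. List medians were 0.62 for resorption, 0.067 for fusion, -0.52 for macrophage, -0.90 for SASP and -1.30 for neutrophil genes.

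Unprefixed KO against set D1 WT gave 11277 genes, with -0.84 for Dcn, -0.37 for Eda2r, 0.88 for Dkc1, 1.97 for Ccnb1 and 2.20 for Cdc20. Medians were 0.18 (RANK signalling), -0.77 (coupling factors), 0.62 (telomere), 0.60 (DNA repair), 2.05 (cell cycle), 0.71 (ribosomal) and -2.52 (stromal).

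Set 519 KO against set D1 WT gave 9536 genes, with -0.64 for Rasgrp2, -0.10 for Dcn, -0.56 for Ctsh, -1.06 for Mmp13, -0.46 for Eda2r, 0.062 for Dkc1, 0.83 for Ccnb1, 1.17 for Cdc20 and -2.83 for Lcn2. Medians were 0.12 (RANK signalling), -0.64 (coupling factors), -0.30 (macrophage), -1.79 (SASP), 0.24 (telomere), 0.13 (DNA repair), 0.71 (cell cycle), 0.39 (ribosomal), -1.37 (neutrophil) and -2.69 (stromal). Cdkn2a passed with set 519 KO against unprefixed WT (1.24), against set D1 WT (1.19) and with both sets on each side (0.66). With both sets on each side Cdc20 was at 0.073 and Lcn2 at -0.68, and medians were -0.27 (coupling factors), -0.38 (SASP), 0.042 (cell cycle), 0.030 (ribosomal), -0.45 (neutrophil) and -1.15 (stromal).

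At 6 months, set 519 KO against unprefixed WT gave 0.66 for Calcr, 0.020 for Steap4, 0.53 for Mmp9, 1.57 for Itgb3, -0.10 for Rrm2, 0.70 for Oscar, 0.63 for Acp5 and 0.14 for Dcstamp. Medians were 0.23 (resorption), 0.19 (fusion), 0.12 (V-ATPase), -0.29 (telomere), -0.56 (cell cycle), 0.028 (nuclear oxidative phosphorylation), -0.29 (heat shock) and 0.036 (histones). With both KO sets the cell cycle median was -0.082.

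With set D1 as 1-month WT, medians for genotype and age, WT at 6 vs 1 and WT at 20 vs 1 month, in this order, were 1.24, -0.52 and -0.50 (resorption), 0.25, -0.15 and -0.28 (V-ATPase), -0.23, 0.46 and 0.97 (interferon), and -0.22, -0.037 and 0.095 (cell cycle inhibitors, in the second by camera's direction). They were -1.63, 1.94 and 1.76 (cell cycle), 0.66, -0.91 and -1.08 (mitochondrial transcripts), -0.57, 0.62 and 0.59 (ribosomal), and 1.05, -0.74 and -0.27 (stromal). Mmp9 was at 2.65, -1.30 and -1.06 and Rrm2 at -1.20, 1.46 and 1.18. For genotype and age medians were -0.35 (telomere) and -0.52 (DNA repair), with 0.91 (Akr1c18), 1.95 (Itgb3), -0.31 (Irf7), -1.68 (Cdc20), 0.66 (mt-Co1) and 1.23 (Col6a1). At 6 vs 1 month heat shock genes had 0.48, with -0.61 (Calcr), -0.99 (Itgb3), 0.68 (Irf7), 0.067 (Ccl2), -0.37 (Dcn) and -0.74 (Pdgfrb). At 20 vs 1 month medians were 0.32 (telomere), 0.69 (DNA repair), -0.082 (glycolysis) and 0.28 (unfolded protein), with -0.62 (Calcr), -1.58 (Clic5), -1.33 (Itga2), -1.27 (Pmaip1), 0.11 (Hmga1) and 0.70 (Pcna), and -0.24 (Pdk1), -0.14 (Vegfa), -0.56 (Col1a1), -0.73 (Ctsk), -1.10 (Acp5) and -1.01 (Dcstamp). The correlation of KO vs WT at 6 months with WT at 20 vs 1 month was 0.039, and that of KO vs WT at 1 month with WT at 20 vs 6 months -0.30. With set D1, 4 gene and 2 list calls were lost without reversal. With set 519 as KO of both ages 0 results reversed, and 2 list calls were lost. The cause was not tested.

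Depth limits the counts of genes. With all libraries thinned, 2178 genes passed for KO vs WT at 1 month, 4344 at 6 months and 2755 for their interaction. For WT, 4653 passed at 6 vs 1 month, 301 at 20 vs 6 months, 5246 at 20 vs 1 month and 356 in 2-day cultures. For KO with age 1724 passed, and 1749 in set 519. For the step from 2 days 3138 passed at 6 months, 3263 at 20 months and 226 for the interaction. Between title sets 3075, 3085 and 6425 passed. Thinning, which leaves fewer counts per gene, lost the calls of Eda2r (1.18 against 1.58), Cdsn (1.99 against 2.24), Aqp1 (1.79 against 1.89), H2-Ab1 (1.595 against 1.57), Mcm5 (-0.20 against -0.37) and, for stage and age, Calcr (-0.93 against -1.33), Top2a (-0.37 against -0.43) and P4ha2 (1.21 against 1.31).

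With only the compared groups in the fit, 3332 genes passed for WT at 20 vs 6 months and 2868 for the interaction of stage and age, which had 3154 with the length trend removed. Shares of higher genes that turned by over 10 points stand with their comparisons. With the trend removed 38.4% were higher against 49.9% for WT at 20 vs 1 month, and with thinning 71.7% against 60.8% for the interaction and 64.5% against 51.7% for WT at 20 vs 6 months. The cause was not tested.

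Leaving out each library in turn gave 1343 to 1947 genes for WT at 20 vs 6 months and 1739 to 2630 in 2-day cultures, and each other count stayed within 1.5 times. Replicate numbers were not taken to pair the samples: same-numbered libraries of different groups correlated at -0.15 to 0.26 and others at -0.27 to 0.20. The 0.26, between 1-month KO and WT libraries numbered 1, lies above the second range. With the replicate block all 15 counts stayed within 1.5 times, and 4 list calls were lost: NRF2 for genotype and age (adjusted p = 0.066), erythroid in 2-day cultures (0.063), and ribosomal (0.062) and erythroid (0.073) for stage and age.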

Other observations

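The tests of sex and of the copy Eif2s3x and the count of splits below were chosen after the results were seen.

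Both 1-month KO sets shared features with no other group. The predicted gene Gm47015 had 595 counts there, the predicted gene Gm8189 310 and the vomeronasal receptor Vmn2r96 118, and each had 0 in the other 24 libraries. Eif2s3y stood at 0.28 of its level in the 6-month KO sets. Cells of the other sex are argued against, since Ddx3y, Kdm5d and Uty had a median ratio of 0.83, and so are reads moved to Eif2s3x, which was lower by a difference of -9.31 CPM. A strain or donor variant stays open: of 254 genes that separate these sets from all other libraries by a log2 difference of 1 or more, 33.1% had another within 1 Mb, against a median of 31.9% in 10000 random sets (one-sided p = 0.38 by permutation of the set over the tested genes). Other pairs of groups had more such genes: 673 for the 2-day WT groups and 290 for set D1 with the 1-month KO of set 519.

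Across title sets and ages, 228 genes separated all libraries of the 4 KO groups from all libraries of the 4 multinucleated WT groups, 177 higher and 51 lower in KO, and 209 of them also separated KO from the 2-day WT libraries. Maoa, a monoamine-degrading enzyme, had the widest gap, with a mean log2 difference of 1.80, followed by Cd55, Als2cl and Npdc1. Of 35 splits of the 8 groups into 4 and 4, 4 gave as many genes, and the highest other gave 1178, for the unprefixed 1-month groups and 6-month KO with the 1-month KO of set 519. Chance therefore cannot be excluded, and that count points to a structure of the samples beyond genotype.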
